A study of Rattus norvegicus with 24 samples.

How the data were processed

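Liver RNA of 24 male Sprague Dawley rats was measured on 24 one-colour arrays, 1 rat per array. The rats formed 4 groups of 6: ANIT or corn oil vehicle, with necropsy 24 h or 120 h after 1 oral dose. ANIT, alpha-naphthylisothiocyanate, is a compound that injures bile duct epithelium and hepatocytes in rodents, and it was given at 50 mg/kg. Groups came from the description label of each sample. Replicate numbers only name rats in accession order and pair none of them across groups. The number of arrays, 6 per group, limits the precision of every value.

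The deposited table holds log2 expression values per probe set, with RMA and Partek named in the submitters' processing notes. Their versions, their settings and the annotation are not given in the sources used here. The 24 columns held 31139 probe sets, with values between 2.34 and 13.5. Array means lay between 5.86 and 5.89, while array medians ran from 5.34 to 5.54 and array SDs from 1.84 to 2.09, so the columns did not share 1 distribution. The values were used as deposited.

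Gene names came from the platform annotation table, updated through Entrez identifiers against a current rat gene table of another assembly, which served for names only. No coordinates are given. Of the probe sets, 19068 named 1 gene, 573 named several and 11498 were without a listed gene. The update renamed 0 probe sets, and 79 kept the annotation's own name. Probe sets naming several genes were not used for named genes. Each of 13438 genes was represented by its probe set with the highest mean over all arrays.

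A cell-means model of the 4 groups was fitted to the log2 values with limma 3.58.1 in R 4.3.3, using lmFit and eBayes. The contrasts were ANIT minus vehicle at 24 h, ANIT minus vehicle at 120 h, the difference between those effects, and vehicle at 120 h minus vehicle at 24 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold. Changes are log2 differences of group means with the standard error of the moderated fit, and folds are their antilogs. The figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

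The 31 gene lists, 14 main lists and 17 other lists, were written down before the data were examined, as were the comparisons, tests, alternatives and the rule for named genes. They hold 641 genes, of which 557 were measured. The main lists were bile acid synthesis, hepatocyte uptake transporters, hepatocyte efflux transporters, cytochrome P450 and phase I, the oxidative stress response of Nrf2 targets, acute phase proteins, chemokines with cytokines and adhesion molecules, neutrophil markers, cholangiocyte and ductular markers, stellate cell with fibroblast and matrix genes, DNA replication, mitosis, cholesterol synthesis, and monocyte and macrophage markers. The other lists were Kupffer cell markers, lymphocyte and NK cell markers, endothelial markers, erythroid genes, pancreatic acinar genes, hepatocyte secreted proteins, nuclear receptors and bile acid sensing, fatty acid synthesis, fatty acid oxidation and ketogenesis, urea cycle and amino acid catabolism, gluconeogenesis and glycolysis, the growth hormone axis with male-predominant genes, immediate early genes, p53 targets, ER stress and amino acid response, interferon response, and circadian clock genes. Lists were tested against all other genes with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 31 lists. Camera with an estimated correlation and fry were alternatives. The p of fry asks whether the genes of a list move one way on balance, and its mixed p whether they change in either direction. Neither compares a list with other genes. Members of a list were also counted with the adjustment over the list alone.

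Named genes followed a fixed rule: the 8 largest rises and the 8 largest falls among called genes whose 6 ANIT arrays all lay beyond all 6 vehicle arrays of that time, the 4 members of each main list and the 2 of each other list with the smallest p, and Cyp7a1, Abcb11, Slc10a1, Nr0b2, Krt19, Mki67, Col1a1 and Hmox1 in every comparison. The difference between times and the vehicle groups gave up to 5 genes per direction. The rule allowed the text to name a part of the list members, and that part, like the few genes named outside the rule, was picked after the values had been seen.

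The models were tested on simulated data with 13438 genes and known changes. At 24 h with independent noise, the group model recovered 48% of log2 changes of 0.5 and 90% of those of 1. It made 5 false calls, 3.50% of calls. At 120 h it recovered 39% and 90%, with 8 false calls, 5.84%. Where simulated genes also followed the level of spiked controls as the real genes do, the group model made 25 false calls at 24 h, 15.9% of calls, against 15, 8.67% of calls, with the control level as a covariate. At 120 h the covariate gave 13 false calls, 7.22% of calls, against 2, 1.41%. Camera called the shifted list in 20 of 20 simulations with independent noise and made 1 other call. Genes of a list were not correlated in these simulations, so they say nothing of false calls among correlated genes.

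The first principal component followed the spread of values within an array, so alternatives were added after seeing the data. They are the SD of an array's values as a covariate the mean level of 9 spiked hybridisation control probe sets as a covariate, 3 bands of array SD as a block, the fit without the 6 narrow arrays, and fits on only the 9 wide or only the 9 middle arrays. The beta-actin 3'/5' ratio and the mean of 3 standardised 3'/5' control ratios, which are signs of RNA quality, were added as covariates too, as was the former together with the control level. Bands were split at the largest gaps, at SDs of 1.92 and 2.01. Alternatives fixed beforehand were another quantile normalization, a shift of each array to a common median, a filter on dim genes, the mean of all probe sets of a gene, every probe set on its own, an intensity trend with a robust prior, array weights, no moderation of the variance, minimum folds of 1.5 and 2, only the arrays of the groups compared, and leaving out each array in turn. Single comparisons between groups of 6 used two-sided exact permutation tests over 924 assignments. Correlations over 24 arrays used permutation tests with 100000 permutations. Counts of calls were set against 100 splits drawn from the 462 possible splits of the 12 arrays compared. For the difference between times, the 12 arrays of each time were split at once.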

Results

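Gene expression was measured in the liver of male Sprague Dawley rats killed 24 h or 120 h after a single oral dose of ANIT at 50 mg/kg or of corn oil. Each of the 4 groups held 6 separate rats on 6 arrays. ANIT damages bile duct epithelium and the hepatocytes around it, and the labels call 24 h the time of peak injury and 120 h that of its resolution. The comparisons ask which genes differed from vehicle at each time, whether that effect differed between times and whether the vehicle groups did. Values are log2 expression values. Each change is given with its standard error (n = 6 and 6 arrays), and adjusted p values come from limma with Benjamini-Hochberg adjustment over 13438 genes. List members are counted over all genes tested and, where stated, adjusted over the list alone.

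The arrays differed in a way that the groups explained only in part. The first principal component held 37.3% of the variance over genes and followed the SD of the values on an array. It also followed the level of 9 spiked hybridisation controls, which ranged from 10.5 to 11.7 over the 24 arrays (Pearson r = 0.92, Spearman rho = 0.91, permutation p = 1e-05 for both, the smallest the permutations can give, adjusted p = 5e-05 over 5 relations). Without the 2 arrays farthest from the median of the control level, r was 0.91. Within the 6 narrow, 9 middle and 9 wide arrays, r was 0.42, 0.29 and 0.22, over a range that is narrower because the bands were formed from array SD (r with the control level -0.97). The component averaged -20.0 ± 16.2 (SD, n = 6) in ANIT and 13.1 ± 22.5 in vehicle rats at 24 h (exact permutation p = 0.022, adjusted p = 0.044 over 13 tests). At 120 h it averaged 9.70 ± 24.5 and -2.77 ± 15.3 (exact permutation p = 0.27). The control level averaged 11.16 ± 0.38 (SD, n = 6) in vehicle and 10.81 ± 0.25 in ANIT rats at 24 h (exact permutation p = 0.091), and 10.86 ± 0.21 and 11.01 ± 0.43 at 120 h (exact permutation p = 0.46). The narrow arrays were 3 of vehicle at 24 h and 3 of ANIT at 120 h, so values with the control level in the model stand beside those of the groups alone. In ANIT rats of 120 h, replicates 1 to 3 had wide and replicates 4 to 6 narrow arrays. No label used here gives a hybridisation or scan batch, so whether the bands are batches was not settled.

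The log2 3'/5' ratio of the beta-actin control, a sign of RNA quality, averaged 3.12 ± 0.07 (SD, n = 6) in ANIT and 2.84 ± 0.05 in vehicle rats at 24 h, above every vehicle rat in 6 of 6 (exact permutation p = 0.0022, adjusted p = 0.017 over 8 tests), so ratio and group were not fully separated there. At 120 h it averaged 2.76 ± 0.15 and 2.83 ± 0.08 (exact permutation p = 0.37). The GAPDH ratio was 1.62 ± 0.04 in ANIT and 1.71 ± 0.08 in vehicle rats at 24 h (exact permutation p = 0.048, adjusted p = 0.16), the other way round. The hexokinase ratio had an exact permutation p of 0.38 and 0.28. The mean of 3 standardised ratios had an exact permutation p of 0.36 at 24 h and 0.061 at 120 h (adjusted p = 0.44 and 0.16). With the beta-actin ratio in the model 907 genes were called at 24 h and 191 at 120 h, 847 and 176 of them calls of the groups alone with the same sign. With the mean ratio 2181 and 156 were, 2070 and 141 of them shared. With the beta-actin ratio and the control level 1833 and 627 were called.

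**Figure D1:**
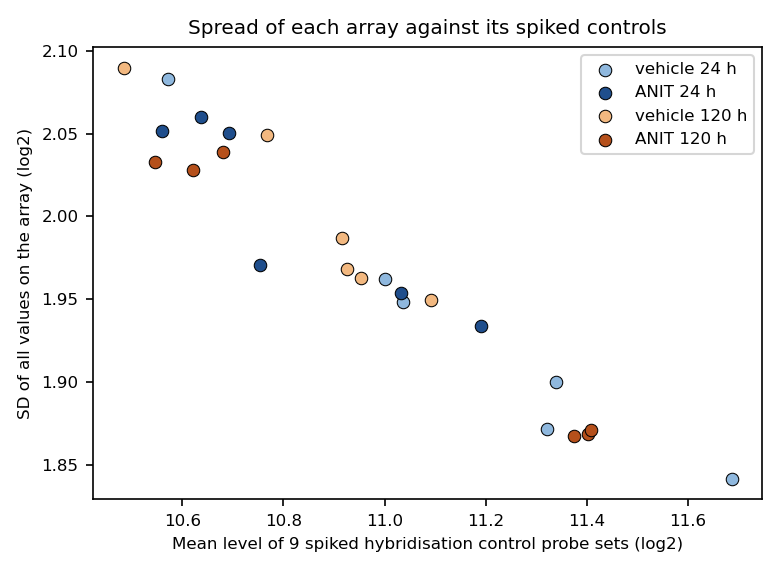
Each point is 1 array, with the mean level of 9 spiked hybridisation control probe sets (log2) on the horizontal axis and the SD of all values on that array (log2) on the vertical axis, coloured by group. Array SDs ran from 1.84 to 2.09 and fell along the control level, with 3 ANIT arrays of 120 h among the 6 narrow and 3 among the 9 wide arrays.

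At 24 h, the livers of ANIT rats showed a rise of acute phase, cholesterol synthesis and endoplasmic reticulum stress genes, and lower expression of bile acid synthesis and hepatocyte uptake transporter genes. Fatty acid oxidation genes were lower too, without a call with an estimated correlation (adjusted p = 0.093). The largest rise was that of Lcn2, the acute phase protein lipocalin-2, which rose 40.1-fold (log2 change 5.33 ± 0.36, adjusted p = 2.8e-10). A2m, the acute phase protein alpha-2-macroglobulin, rose 15.5-fold (3.95 ± 0.32, adjusted p = 4.3e-09), and Cyp1a1, a drug-metabolising enzyme, rose 10.1-fold (3.34 ± 0.22, adjusted p = 2.8e-10). The largest fall was that of Nrep (-4.45 ± 0.31, 21.9-fold, adjusted p = 3.2e-10). Hsd17b2, which inactivates sex steroids, fell by 3.25 ± 0.30, and Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, fell by 2.45 ± 0.23.

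Further large rises were those of Amigo3 (2.97 ± 0.27), Sqle (2.83 ± 0.19), Fer1l5 (2.82 ± 0.28), Idi1 (2.81 ± 0.25) and Fasn (2.76 ± 0.20), of which Sqle and Idi1 act in cholesterol synthesis and Fasn in fatty acid synthesis. Further large falls were those of Nim1k (-2.78 ± 0.33), Cyp17a1 (-2.24 ± 0.32), Fmo1 (-2.22 ± 0.18), Serpina6, the corticosteroid-binding globulin (-2.16 ± 0.18), and Nox4 (-2.03 ± 0.26). The highest adjusted p among these 10 genes was that of Cyp17a1 (limma, 1.3e-05). In each of them the 6 ANIT arrays lay beyond the 6 vehicle arrays. Such a separation was found in 1057 genes at 24 h, where chance gives 0.216% of genes, or 29.1.

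In all, 2451 of 13438 genes were called at 24 h, 1738 higher and 713 lower, and 206 and 87 of them changed at least 2-fold. With the control level in the model 2700 genes were called, 1293 higher and 1407 lower. The 2 fits shared 1850 calls of the same sign and 0 of opposite sign. The share of higher calls was thus 70.9% as deposited and 47.9% with the control level, and it was 81.2% after shifting the arrays to a common median, 50.9% with the beta-actin ratio and 48.2% with that ratio and the control level. The balance of rises and falls is not settled by these data. Called genes had the same sign in 99.7% of cases within the middle arrays (3 ANIT, 2 vehicle) and in 97.6% within the wide arrays (3 ANIT, 1 vehicle), which are among the arrays that made the calls.

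Genes of sterol synthesis, protein folding stress and the acute phase rose together. Of 19 measured cholesterol synthesis genes 17 rose, 0 fell and 2 were not called, 18 rising when adjusted over the list alone, with a median change of 0.99 (camera adjusted p = 1.3e-16). Among them, Lss rose by 2.18 ± 0.22 and Insig1, which restrains sterol synthesis, by 1.47 ± 0.15. Of 22 ER stress and amino acid response genes 15 rose, 0 fell and 7 were not called, 17 rising when adjusted over the list alone (median 0.77, adjusted p = 6.3e-16). Creld2 rose by 2.57 ± 0.18 and the chaperone Hyou1 by 1.92 ± 0.14. Of 23 acute phase proteins 19 rose, 0 fell and 4 were not called, 20 rising when adjusted over the list alone (median 0.36, adjusted p = 8.6e-12). Orm1 rose by 0.95 ± 0.10 and Saa4 by 0.70 ± 0.08. These 3 calls also held with an estimated correlation (adjusted p = 0.014, 0.011 and 0.0015). Their medians in the model with the control level were 0.95, 0.71 and 0.38.

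Fatty acid synthesis, immediate early and oxidative stress genes also rose as lists. Of 16 fatty acid synthesis genes 5 rose, 1 fell and 10 were not called, with the same counts adjusted over the list alone (median 0.30, camera adjusted p = 0.0023, adjusted p = 0.16 with an estimated correlation). Acaca, which makes malonyl-CoA, rose by 1.10 ± 0.13. Of 22 immediate early genes 9 rose, 0 fell and 13 were not called, 14 rising and 1 falling when adjusted over the list alone (median 0.49, adjusted p = 0.00054, adjusted p = 0.094 with an estimated correlation). Atf3 rose by 2.00 ± 0.31 and Gadd45b by 1.5 ± 0.25. Of 21 Nrf2 targets 11 rose, 1 fell and 9 were not called, with the same counts adjusted over the list alone (median 0.45, adjusted p = 0.0077, adjusted p = 0.35 with an estimated correlation, and median 0.28, adjusted p = 0.044 with the control level). Gsta3, a glutathione transferase, rose by 2.02 ± 0.39, Nqo1 by 1.59 ± 0.25, Me1 by 0.96 ± 0.22, the haem-degrading enzyme Hmox1 by 0.77 ± 0.18 and Pgd by 0.58 ± 0.11. The Nrf2 list lost its call after another quantile normalization and with the band of arrays as a block, and the immediate early and Nrf2 lists lost theirs when dim genes were left out.

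Bile acid synthesis genes and hepatocyte uptake transporters fell as lists. Of 12 bile acid synthesis genes 0 rose, 7 fell and 5 were not called, 8 falling when adjusted over the list alone (median -0.48, camera adjusted p = 1.1e-06, adjusted p = 0.00090 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of the classic pathway, fell by 1.78 ± 0.44 (adjusted p = 0.0057), Amacr by 0.72 ± 0.11, Cyp27a1 by 0.71 ± 0.08 and Baat by 0.33 ± 0.07. Of 7 uptake transporters 0 rose, 5 fell and 2 were not called, as also when adjusted over the list alone (median -0.54, adjusted p = 1.6e-05, adjusted p = 0.014 with an estimated correlation). Slc10a1, the sodium-dependent bile acid carrier, fell by 0.54 ± 0.08, Slco1b2 by 0.59 ± 0.10, Slco1a4 by 1.39 ± 0.25 and Slc22a5, a carnitine carrier, by 1.12 ± 0.19. The efflux transporters went both ways: of 13, 5 rose, 2 fell and 6 were not called, also when adjusted over the list alone (median -0.02, mean 0.18, adjusted p = 0.70). Abcb11, the bile salt export pump, rose by 0.45 ± 0.11, Abcb4 by 0.76 ± 0.13 and Abcg2 by 1.41 ± 0.20, while the sterol exporter gene Abcg5 fell by 0.98 ± 0.18. Nr0b2, a repressor of bile acid synthesis genes, rose by 2.35 ± 0.25, and Nr1h4, the bile acid receptor FXR, fell by 1.16 ± 0.20. Without the 6 narrow arrays, Cyp7a1 and Abcb11 were not called.

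Of 19 fatty acid oxidation and ketogenesis genes 0 rose, 12 fell and 7 were not called, the same counts as adjusted over the list alone (median -0.42, camera adjusted p = 7.5e-11, adjusted p = 0.093 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, fell by 1.06 ± 0.11 and the ketone body enzyme Bdh1 by 1.21 ± 0.16. Of 17 genes of the growth hormone axis and male-predominant genes 1 rose, 7 fell and 9 were not called, 8 falling when adjusted over the list alone (median -0.25, adjusted p = 0.00086, adjusted p = 0.014 with an estimated correlation). Cyp3a2 fell by 0.68 ± 0.09. The 17 measured cytochrome P450 and phase I genes went both ways: 4 rose, 7 fell and 6 were not called, 5 rising and 7 falling when adjusted over the list alone (median -0.20, adjusted p = 0.048, adjusted p = 0.33 with an estimated correlation, 0.073 with the control level). Cyp2a2 fell by 0.73 ± 0.08, while Fmo5 rose by 0.66 ± 0.09. The P450 call also ended with the array SD as a covariate and with the band as a block (adjusted p = 0.069 and 0.082). It ended without vehicle 24 h replicate 1 (adjusted p = 0.13, the highest), and also without vehicle 24 h replicate 2, 4 or 6, ANIT 24 h replicate 3, 4 or 5, vehicle 120 h replicate 1, 3, 4 or 5, or ANIT 120 h replicate 4, 5 or 6.

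Proliferation genes and lymphocyte markers were lower as lists, with few single calls. Of 31 mitosis genes 0 rose, 3 fell and 28 were not called, 2 falling when adjusted over the list alone (median -0.22, camera adjusted p = 0.00024, adjusted p = 0.17 with an estimated correlation, and median -0.08, adjusted p = 0.053 with the control level). Hmmr fell by 0.42 ± 0.12, and its call was lost after another quantile normalization, after the median shift and without the 6 narrow arrays. Mki67 had a value of -0.57 ± 0.44 (adjusted p = 0.40). Without vehicle 24 h replicate 1 it was -1.03 (adjusted p = 0.031). Of 26 DNA replication genes 1 rose, 3 fell and 22 were not called, also when adjusted over the list alone (median -0.14, adjusted p = 0.040, adjusted p = 0.071 with an estimated correlation, 0.15 with the control level). Uhrf1 fell by 0.54 ± 0.13 and Mcm10 by 0.40 ± 0.11, calls that were lost without the 6 narrow arrays and after another quantile normalization (adjusted p = 0.16 and 0.051). That list's call was also lost after another quantile normalization, with probe set means, when dim genes were left out, with the array SD or the band in the model and without the 6 narrow arrays (adjusted p from 0.063 to 0.21). It was lost without vehicle 24 h replicate 4 or 5 or ANIT 24 h replicate 1 or 3, with an adjusted p of up to 0.084. Of 16 lymphocyte and NK cell markers 0 rose, 2 fell and 14 were not called, also when adjusted over the list alone (median -0.19, adjusted p = 0.0077, adjusted p = 0.040 with an estimated correlation). These were Cd8a (-0.56 ± 0.14), whose 3 probe sets ran from -0.56 to 0.04 (mean -0.23, adjusted p = 0.066), and Cd79b (-0.32 ± 0.10), and Cd79b lost its call with the control level (adjusted p = 0.078), and without vehicle 24 h replicate 3, 5 or 6 or ANIT 24 h replicate 2, 5 or 6 (adjusted p up to 0.072). The lymphocyte list lost its call after another quantile normalization and with the band of arrays as a block (adjusted p = 0.14 and 0.054).

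Markers of other cell types and of inflammation were not called as lists at 24 h, though single members rose. Of 29 chemokines, cytokines and adhesion molecules 7 rose, 1 fell and 21 were not called, 7 rising and 2 falling when adjusted over the list alone (median 0.05, camera adjusted p = 0.15, and 0.040 with the control level). Tnfrsf12a rose by 2.15 ± 0.24, Icam1 by 1.38 ± 0.22, Ccl2 by 1.20 ± 0.24 and Cxcl2 by 0.65 ± 0.15. Of 12 neutrophil markers 4 rose, 0 fell and 8 were not called, 5 rising and 1 falling when adjusted over the list alone (median 0.02, adjusted p = 0.26, and median 0.10, adjusted p = 0.042 without the 6 narrow arrays). They included S100a8 (1.82 ± 0.38), S100a9 (0.87 ± 0.22) and Il1r2 (0.84 ± 0.16). Of 19 monocyte and macrophage markers 5 rose, 0 fell and 14 were not called, also when adjusted over the list alone (median 0.13, adjusted p = 0.26). Lgals3 rose by 1.13 ± 0.23 and S100a4 by 0.83 ± 0.18. Of 25 cholangiocyte and ductular markers 4 rose, 3 fell and 18 were not called, also when adjusted over the list alone (median -0.09, mean 0.09, adjusted p = 0.70). The risers Krt18 (1.16 ± 0.13) and Krt8 (1.07 ± 0.18) are keratins that hepatocytes also make, and Slc10a2 (2.73 ± 0.35) is a bile acid carrier. Krt19, a keratin of bile duct cells, had a value of -0.16 ± 0.12 (adjusted p = 0.39). Of 33 stellate cell, fibroblast and matrix genes 5 rose, 3 fell and 25 were not called, 6 rising and 4 falling when adjusted over the list alone (median 0.03, adjusted p = 0.80). Timp1 rose by 1.86 ± 0.24 and Fn1 by 0.36 ± 0.08. Lrat, a retinol-storing enzyme of stellate cells, fell by 1.25 ± 0.17. Col1a1 had a value of 0.01 ± 0.24 (adjusted p = 0.99).

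The other 11 lists were not called at 24 h either. The members that rose and fell were 2 and 3 of 16 circadian clock genes (median -0.16, camera adjusted p = 0.11), with Tef at -1.31 ± 0.13 and Hlf at -1.03 ± 0.16, and 2 and 3 of 17 gluconeogenesis and glycolysis genes (median -0.07, adjusted p = 0.33), with G6pc1 at -1.66 ± 0.19. They were 5 and 7 of 22 urea cycle and amino acid catabolism genes (median -0.09, adjusted p = 0.26, and 0.044 with the control level), 1 and 2 of 21 hepatocyte secreted proteins (median -0.05, adjusted p = 0.11), and 2 and 2 of 14 nuclear receptor genes (median 0.03, adjusted p = 0.77). They were also 1 and 3 of 14 endothelial markers (median -0.09, adjusted p = 0.33, and 0.022 with the control level), 2 and 1 of 9 Kupffer cell markers (median 0.02, adjusted p = 0.77), and 5 and 2 of 16 p53 targets (median 0.04, adjusted p = 0.95). For the 21 interferon response genes they were 4 and 1 (median 0.01, adjusted p = 0.77), for the 11 pancreatic acinar genes 1 and 1 (median -0.15, adjusted p = 0.26), and for the 5 erythroid genes 0 and 0 (median -0.09, adjusted p = 0.51). When dim genes were left out, the secreted protein, urea cycle and circadian lists were called (adjusted p = 0.013, 0.042 and 0.033), and without the 6 narrow arrays the circadian, urea cycle and endothelial lists were (adjusted p = 0.046, 0.018 and 0.046). Adjusted over the list alone these counts were the same, except 6 and 8 urea cycle genes, 3 and 3 nuclear receptor genes and 5 and 1 interferon response genes. Camera's direction was opposite to a positive median and mean for the stellate cell, nuclear receptor and p53 lists, followed the median but not the mean for the cholangiocyte list, and followed the mean but not the median for the efflux list.

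In all, 14 of 31 lists were called at 24 h, 6 higher and 8 lower, and 7 were with an estimated correlation. In the model with the control level it was 14 too. Other splits of the same 12 arrays into 6 and 6 called a median of 6 lists and at most 15. With only the middle arrays the P450, Nrf2, DNA replication and lymphocyte lists lost their calls, and with only the wide arrays the DNA replication, mitosis and lymphocyte lists did. With the beta-actin ratio in the model the P450, Nrf2, DNA replication and mitosis lists were not called (adjusted p = 0.17, 0.12, 0.070 and 0.10), and 10 lists were. In that model the calls of Cyp7a1, Abcb11, Baat, Gsta3, Pgd, Me1, Hmox1, Ccl2, S100a9, Krt8, Fn1, Uhrf1, Mcm10, Hmmr, Lgals3 and S100a4 were lost (limma adjusted p from 0.052 for Fn1 to 0.38 for Me1), and Cd79b had a value of 0.0035. With the mean 3'/5' ratio Cd79b and the DNA replication list lost their calls (adjusted p = 0.063 and 0.061). By fry, 21 lists moved one way.

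**Figure D2:**
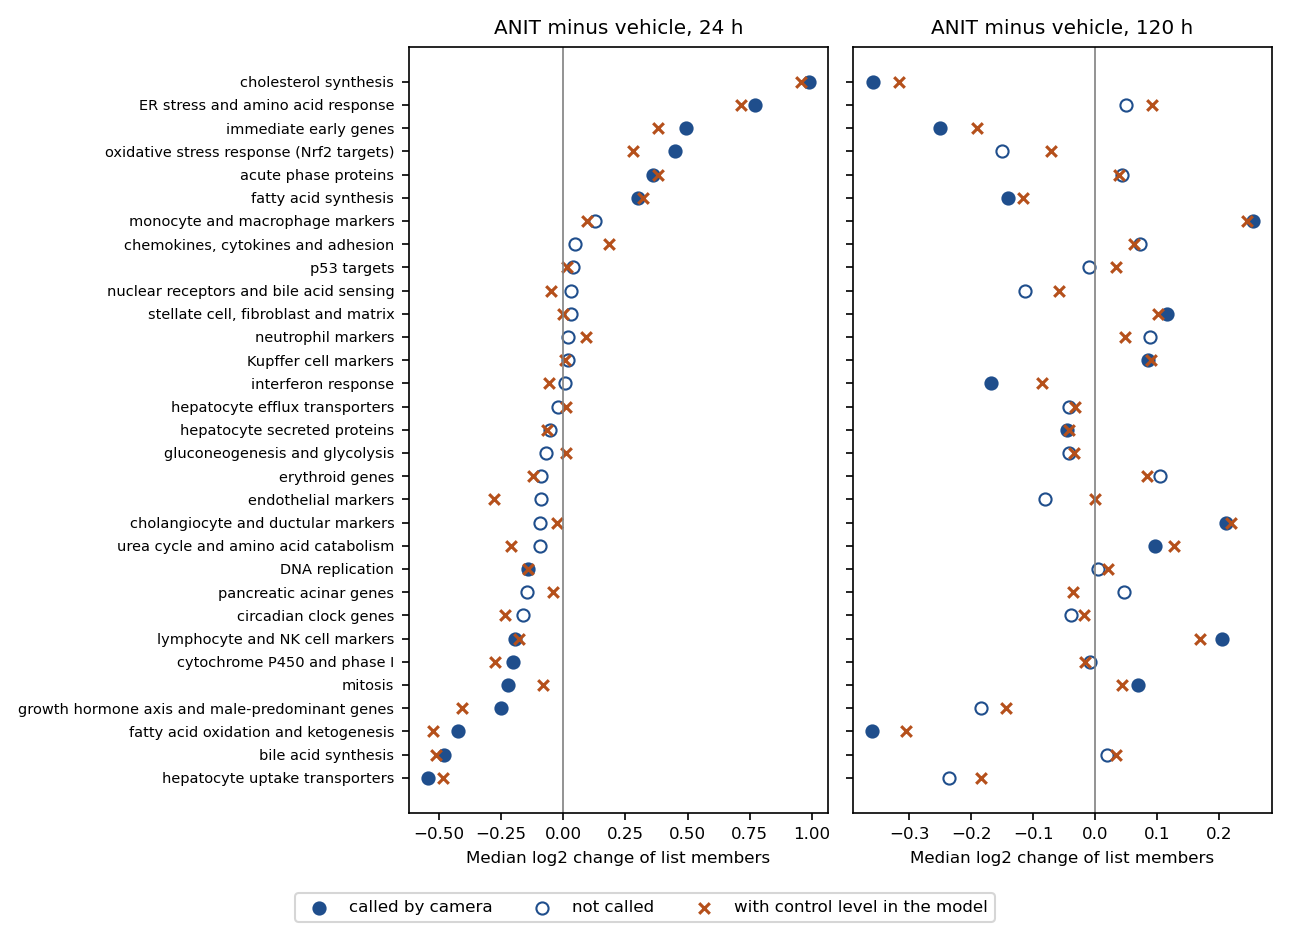
Each line is 1 of 31 fixed gene lists and the horizontal axis is the median log2 change of its measured members, ANIT minus vehicle, at 24 h on the left and at 120 h on the right, with axes of different range. Filled circles were called by camera, open circles were not, and crosses are medians with the level of spiked controls in the model. Cholesterol synthesis lay highest at 24 h, at 0.99, and at -0.36 at 120 h.

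At 120 h fewer genes were called, and the livers showed higher bile duct markers. Macrophage markers were higher and fatty acid oxidation, cholesterol synthesis and fatty acid synthesis genes lower as lists, but these calls were lost with an estimated correlation (adjusted p = 0.092, 0.092, 0.20 and 0.20). The largest rise was that of Serpina7, the thyroxine-binding globulin, which rose 3.72-fold (log2 change 1.90 ± 0.33, limma adjusted p = 0.0025). Lcn2 was still 3.30-fold higher (1.72 ± 0.36, adjusted p = 0.011), and Postn, a matrix protein, rose 2.70-fold (1.43 ± 0.21, adjusted p = 0.00047). The largest fall was that of Inmt, a methyltransferase (-2.43 ± 0.40, 5.37-fold, adjusted p = 0.0014), followed by Egr1, an immediate early transcription factor (-1.93 ± 0.24, 3.8-fold, adjusted p = 8.5e-05).

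Further rises were those of Siglec5 (1.36 ± 0.23), the tubulin Tubb4b (1.26 ± 0.22), Tspan8 (1.14 ± 0.16), Tsx (1.09 ± 0.20) and Pde4b (1.0 ± 0.20). Further falls were those of Paqr9 (-1.77 ± 0.23), Nat8 (-1.61 ± 0.16), Tor3a (-1.60 ± 0.21), the organic anion carrier gene Slc22a8 (-1.57 ± 0.25), the hormone gene Fgf21 (-1.52 ± 0.30) and Car3 (-1.51 ± 0.28). The highest adjusted p among them was that of Pde4b (limma, 0.0084). In 287 genes the ANIT and vehicle arrays did not overlap, where chance gives 29.1.

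In all, 272 genes were called at 120 h, 69 higher and 203 lower, and 10 and 25 of them changed at least 2-fold. The model with the control level called 674, 253 higher and 421 lower. It included all 272 with the same sign. The share of higher calls was 25.4% as deposited, 38.7% with the beta-actin ratio, 39.1% with the mean 3'/5' ratio, 37.5% with the control level, 41.5% after another quantile normalization, 53.1% with array weights and 73.2% without the 6 narrow arrays. Within the wide arrays (3 ANIT, 2 vehicle), which helped make these calls, 100% of the 272 had the same sign. The count fell to 165 and 152 without vehicle 120 h replicate 3 and 5. It fell to 167, 165 and 153 without ANIT 120 h replicate 4, 5 and 6.

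Markers of bile duct cells rose at 120 h. Of 25 measured members 4 rose, 0 fell and 21 were not called, 7 rising when adjusted over the list alone (median 0.21, camera adjusted p = 5.4e-10, adjusted p = 4.4e-05 with an estimated correlation, and median 0.22, adjusted p = 3.6e-09 with the control level). Krt19 rose by 0.73 ± 0.12, Cd24 by 0.72 ± 0.11, the stem and duct cell marker Prom1 by 0.66 ± 0.13 and the chloride channel gene Cftr by 0.49 ± 0.12 (adjusted p = 0.037). The mean of the list, set against the vehicle mean of 120 h, was 0.30 ± 0.09 (SD, n = 6) in ANIT rats, above every vehicle rat in 6 of 6 (two-sided exact permutation p = 0.0022, the smallest of 924 assignments, adjusted p = 0.0094 over 13 tests). Within the wide arrays the median of the list was 0.26.

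Markers of immune and matrix cells were higher as lists, with few single calls. Of 19 monocyte and macrophage markers 1 rose, 0 fell and 18 were not called, also when adjusted over the list alone (median 0.25, camera adjusted p = 9.0e-06, adjusted p = 0.092 with an estimated correlation). The riser was Gpnmb (1.08 ± 0.19). Of 9 Kupffer cell markers 2 rose, 0 fell and 7 were not called, also when adjusted over the list alone (median 0.08, adjusted p = 0.0093, adjusted p = 0.20 with an estimated correlation). These were the iron exporter gene Slc40a1 (0.38 ± 0.08) and the haemoglobin receptor gene Cd163 (0.43 ± 0.10). Of 33 stellate cell, fibroblast and matrix genes 1 rose, 0 fell and 32 were not called, 8 rising when adjusted over the list alone (median 0.12, adjusted p = 5.1e-05, adjusted p = 0.20 with an estimated correlation). The riser was Postn. The collagen genes Col1a1 (0.89 ± 0.24, adjusted p = 0.050), Col5a2 (0.58 ± 0.17, adjusted p = 0.079) and Col1a2 (0.53 ± 0.16, adjusted p = 0.080) were not called as deposited. They were with the control level (adjusted p = 0.034, 0.0063 and 0.038) and after another quantile normalization (adjusted p = 0.029, 0.0085 and 0.027). With every probe set on its own, that used for Col1a1 had an adjusted p of 0.074, and the other was called (0.93 ± 0.22, adjusted p = 0.032). Col1a1 was called without ANIT 24 h replicate 5 (adjusted p = 0.0074), vehicle 24 h replicate 1 or 5 or ANIT 24 h replicate 1. So were Col1a1 and Col1a2 (adjusted p = 0.037) without ANIT 120 h replicate 1 and Col5a2 (0.042) without vehicle 24 h replicate 1. Of 16 lymphocyte and NK cell markers 0 rose, 0 fell and 16 were not called, also when adjusted over the list alone (median 0.20, adjusted p = 0.0019, adjusted p = 0.038 with an estimated correlation). The lymphocyte list was not called without the 6 narrow arrays (median 0.11, adjusted p = 0.052), and with only the wide arrays it, the Kupffer cell list and the stellate cell list were not (adjusted p = 0.12, 0.089 and 0.12).

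At 120 h 3 lists of lipid genes were called lower, each with fewer called than uncalled members. Of 19 fatty acid oxidation and ketogenesis genes 0 rose, 6 fell and 13 were not called, 16 falling when adjusted over the list alone (median -0.36, camera adjusted p = 9.1e-14, adjusted p = 0.092 with an estimated correlation). Ehhadh fell by 0.83 ± 0.17 and Fabp1 by 0.36 ± 0.07. Of 19 cholesterol synthesis genes 0 rose, 5 fell and 14 were not called, 10 falling when adjusted over the list alone (median -0.36, adjusted p = 3.9e-07, adjusted p = 0.20 with an estimated correlation). Cyp51 fell by 0.89 ± 0.19, Nsdhl by 0.55 ± 0.09, Msmo1 by 0.99 ± 0.25 (adjusted p = 0.041) and Sqle by 0.76 ± 0.19 (adjusted p = 0.039). Of 16 fatty acid synthesis genes 0 rose, 3 fell and 13 were not called, 4 falling when adjusted over the list alone (median -0.14, adjusted p = 0.0062, adjusted p = 0.20 with an estimated correlation). Fads1 fell by 1.44 ± 0.18 and Elovl5 by 1.35 ± 0.18. The fatty acid synthesis list was not called when dim genes were left out, and its median within the wide arrays was 0.03.

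Of 22 immediate early genes 0 rose, 3 fell and 19 were not called, also when adjusted over the list alone (median -0.25, camera adjusted p = 0.0058, adjusted p = 0.20 with an estimated correlation). Dusp1 fell by 0.85 ± 0.17, and Egr1 was another. Of 21 hepatocyte secreted proteins 0 rose, 3 fell and 18 were not called, 4 falling when adjusted over the list alone (median -0.05, adjusted p = 0.012, adjusted p = 0.20 with an estimated correlation). The call was lost when dim genes were left out (adjusted p = 0.29) and with the band as a block (0.068). Apoa2 fell by 0.47 ± 0.10 and the coagulation factor gene F10 by 0.30 ± 0.07. Of 22 urea cycle and amino acid catabolism genes 1 rose, 0 fell and 21 were not called, also when adjusted over the list alone (median 0.10, adjusted p = 0.012, adjusted p = 0.38 with an estimated correlation). It was lost with the band as a block (adjusted p = 0.056) and without the 6 narrow arrays (0.085). The riser was Tdo2, which degrades tryptophan (0.43 ± 0.10). Of 21 interferon response genes 0 rose, 1 fell and 20 were not called, also when adjusted over the list alone (median -0.17, adjusted p = 0.0098, adjusted p = 0.38 with an estimated correlation). That gene was Ifi27 (-0.47 ± 0.12). The interferon list lost its call when dim genes were left out (adjusted p = 0.13) and without vehicle 120 h replicate 2 (adjusted p = 0.14) or ANIT 120 h replicate 4. Of 31 mitosis genes 0 rose, 0 fell and 31 were not called, also when adjusted over the list alone (median 0.07, adjusted p = 0.042, adjusted p = 0.38 with an estimated correlation, 0.30 with the control level). Mki67 had a value of 0.39 ± 0.44 (adjusted p = 0.72). The mitosis call ended after another quantile normalization (adjusted p = 0.30) and with the array SD or the band in the model. It ended without ANIT 120 h replicate 4 (adjusted p = 0.14, the highest), ANIT 120 h replicate 3, 5 or 6 or vehicle 120 h replicate 2, 3, 4 or 6. Without the 6 narrow arrays its median was 0.0043 with camera's direction down, and with only the wide arrays it was -0.03.

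The bile acid synthesis, uptake and efflux lists were not called at 120 h. Of 12 bile acid synthesis genes 0 rose, 0 fell and 12 were not called, 2 falling when adjusted over the list alone (median 0.02, mean -0.12, camera adjusted p = 0.61, direction down). Cyp7a1 had a value of -0.82 ± 0.44 (adjusted p = 0.42) and Cyp8b1 one of -0.68 ± 0.23 (adjusted p = 0.13, and 0.0082 with only the 12 arrays of that time). Slc10a1 was at 0.04 ± 0.08 (adjusted p = 0.87), Abcb11 at -0.07 ± 0.11 (adjusted p = 0.80) and Nr0b2 at 0.04 ± 0.25 (adjusted p = 0.97). Of 7 uptake transporters 0 rose and 2 fell (median -0.24, adjusted p = 0.079), among them Slc22a5 (-0.79 ± 0.19). Of 13 efflux transporters 1 rose and 1 fell (median -0.04, adjusted p = 0.81), which were Abcc3, an exporter of bile acids to the blood (0.77 ± 0.15), and Abcg5 (-0.93 ± 0.18).

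The other uncalled lists at 120 h were the 14 nuclear receptor genes (0 rose, 1 fell, median -0.11, camera adjusted p = 0.055), the 17 growth hormone axis genes (0 and 2, median -0.18, adjusted p = 0.071), and the 17 cytochrome P450 genes (0 and 2, median -0.01, mean -0.22, adjusted p = 0.11). Cyp2c11 fell by 1.19 ± 0.20, Igfals by 0.75 ± 0.19 and Cyp1a2 by 0.85 ± 0.12. The acute phase proteins (2 rose, 0 fell of 23, median 0.04, adjusted p = 0.097) included the iron hormone gene Hamp (1.5 ± 0.34). Nrf2 targets (1 and 0 of 21, median -0.15, adjusted p = 0.29) had Hmox1 at 0.58 ± 0.18 (adjusted p = 0.088, and 0.046 without vehicle 24 h replicate 5, 0.049 with the control level and 0.021 without the 6 narrow arrays). DNA replication genes (0 and 1 of 26, mean -0.03, adjusted p = 0.94) had Mcm10 at -0.47 ± 0.11. Chemokines and cytokines (0 and 0 of 29, median 0.07, adjusted p = 0.089), neutrophil markers (0 and 0 of 12, median 0.09, adjusted p = 0.093) and pancreatic acinar genes (0 and 0 of 11, median 0.05, adjusted p = 0.24) had no called member. Nor had circadian clock genes (0 and 0 of 16, median -0.04, adjusted p = 0.61), endothelial markers (0 and 0 of 14, median -0.08, adjusted p = 0.61) and erythroid genes (0 and 0 of 5, median 0.10, adjusted p = 0.75). ER stress genes (0 and 1 of 22, median 0.05, adjusted p = 0.36), gluconeogenesis and glycolysis genes (0 and 1 of 17, median -0.04, adjusted p = 0.38) and p53 targets (0 and 0 of 16, median -0.01, adjusted p = 0.90, camera direction up) were the others. Adjusted over the list alone, 3 uptake transporters, 5 cytochrome P450, 3 growth hormone axis, 2 nuclear receptor and 2 gluconeogenesis genes and 1 p53 target fell and 2 Nrf2 targets rose, with the other counts the same. The P450 list was called without the 6 narrow arrays (median -0.08, adjusted p = 0.0031). When dim genes were left out, the acute phase, chemokine and ER stress lists were called (adjusted p = 0.0019, 0.048 and 0.048). With probe set means the nuclear receptor and growth hormone axis lists were called (adjusted p = 0.017 and 0.035), and the former also after the median shift (0.043). Single arrays made a call when left out: vehicle 120 h replicate 5 for chemokines (adjusted p = 0.028), ANIT 120 h replicate 4 or vehicle 120 h replicate 5 for P450 genes (0.022 at the lowest), vehicle 120 h replicate 3 for the growth hormone axis (0.047) and vehicle 120 h replicate 5 (0.021), ANIT 24 h replicate 1, 3 or 4 or ANIT 120 h replicate 2 or 4 for nuclear receptors.

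In all, 13 of 31 lists were called at 120 h, 7 higher and 6 lower, and 2, the cholangiocyte and lymphocyte lists, were with an estimated correlation. Other splits of the same 12 arrays into 6 and 6 called a median of 2 lists and at most 12. By fry, the mitosis, urea cycle and interferon lists were not called (adjusted p = 0.33, 0.26 and 0.14). With only the wide arrays the immediate early, secreted protein and urea cycle lists were not called either (adjusted p = 0.12, 0.41 and 0.30). Without the 6 narrow arrays the calls of Fgf21, Cftr, Cd163, Cyp51, Sqle, Msmo1, Fabp1, Ehhadh, Slc22a5, Abcg5, Apoa2, Ifi27, Tdo2, F10 and Igfals were lost, with a limma adjusted p from 0.051 for Cd163 to 0.29 for Igfals. With the beta-actin ratio in the model those of Sqle, Msmo1, Ifi27, F10 and Igfals were lost, and with the mean 3'/5' ratio those of Slc22a5, Hamp, Ifi27, Tdo2, F10 and Igfals were. The mitosis list was called in neither model (adjusted p = 0.16 in both), and the interferon list was not with the beta-actin ratio and the control level (adjusted p = 0.071). After the median shift the calls of Cftr, Cd163, Slc40a1, Sqle, Msmo1, Tdo2, F10 and Igfals were lost. Several gene calls were lost when 1 array was left out, given as the highest limma adjusted p with its array first, for replicates of 120 h unless 24 h is named. It was 0.12 for Ifi27 (ANIT 4, also vehicle 2 to 6, ANIT 1, 3 and 5 and vehicle 24 h replicates 2 and 6) and 0.11 for Msmo1 (vehicle 3, also vehicle 1, 2 and 5, ANIT 4, 5 and 6 and vehicle 24 h replicate 2). It was 0.11 for Sqle (vehicle 5, also vehicle 1, 2 and 3 and ANIT 3 to 6), 0.11 for Igfals (vehicle 5, also vehicle 1, 2, 4 and 6 and ANIT 1, 4, 5 and 6) and 0.10 for Cftr (ANIT 4, also vehicle 1, 2, 4, 5 and 6 and ANIT 1, 3 and 6). It was 0.094 for F10 (vehicle 3, also vehicle 2 and 5 and ANIT 4, 5 and 6) and 0.065 for Tdo2 (ANIT 5, also vehicle 1, 5 and 6 and ANIT 4 and 6). It was 0.075 for Cd163 (vehicle 5, also vehicle 1 and 6 and ANIT 6), 0.075 for Slc22a5 (ANIT 5, also vehicle 3 and 5 and ANIT 4 and 6), 0.059 for Mcm10 (ANIT 4, also vehicle 2 and 3) and 0.054 for Hamp (vehicle 3, also vehicle 2 and ANIT 6).

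**Figure D3:**
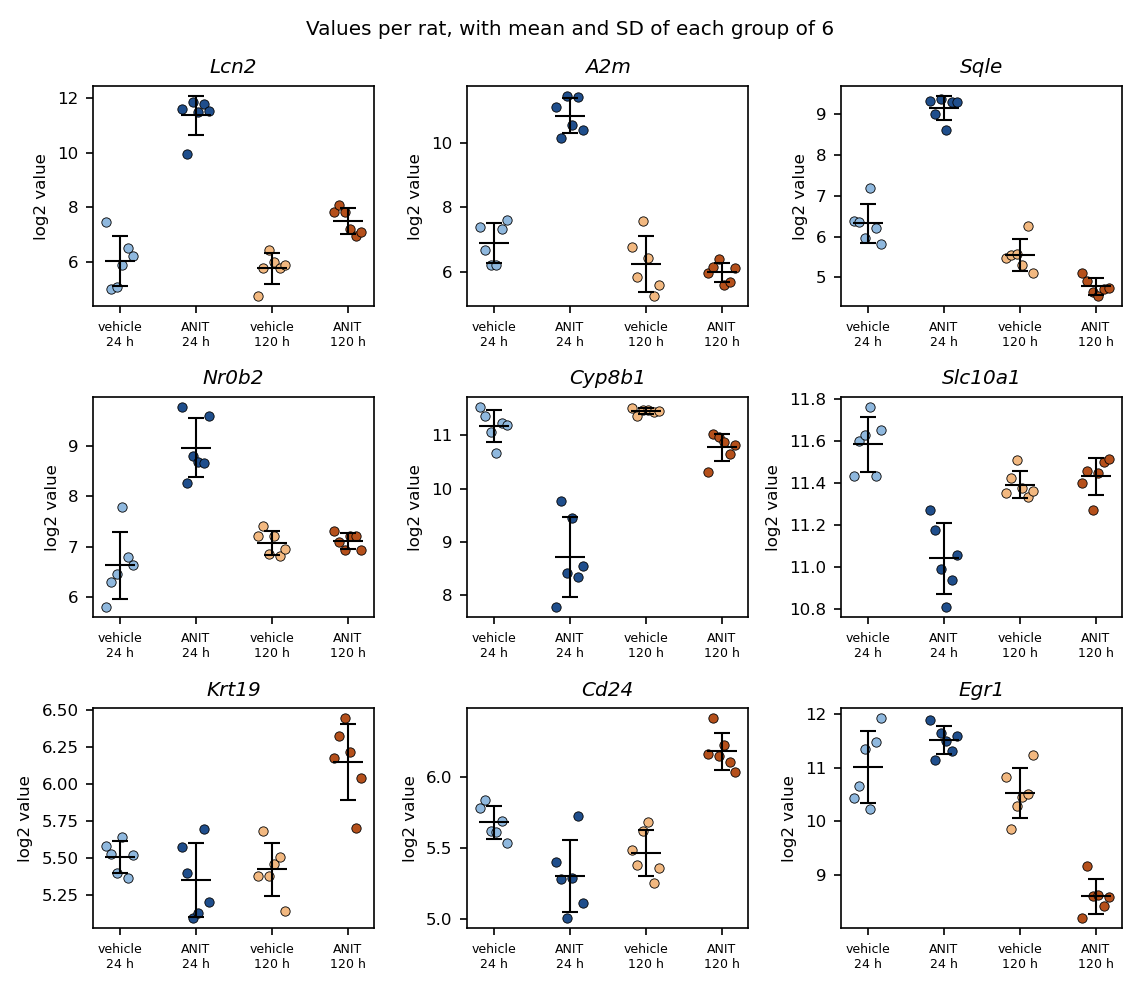
Points are the log2 values of 9 genes in each of 24 rats, by group on the horizontal axis, with the mean and SD of each group of 6 as a bar with caps and vertical axes of different range that do not start at 0. Lcn2 averaged 11.37 in ANIT and 6.04 in vehicle rats at 24 h, and Krt19 averaged 6.15 and 5.42 at 120 h.

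The ANIT effect differed between the times for many genes. Nrep, which had the largest fall at 24 h, had an effect higher at 120 h by 4.22 ± 0.44 (limma adjusted p = 7.7e-07). Siglec5 (2.39 ± 0.32), Hsd17b2 (2.30 ± 0.42), Nim1k (2.27 ± 0.47) and Fmo1 (2.22 ± 0.25) also had a higher effect at 120 h. The effect of A2m fell by 4.21 ± 0.46, that of Lcn2 by 3.60 ± 0.51, that of Sqle by 3.59 ± 0.27, that of Idi1 by 3.41 ± 0.36 and that of Amigo3 by 3.08 ± 0.38. The effect on Krt19 (0.88 ± 0.17) and Slc10a1 (0.58 ± 0.12) was higher at 120 h, and that on Nr0b2 (-2.32 ± 0.35) and Abcb11 (-0.53 ± 0.16, adjusted p = 0.027) was lower. With the beta-actin ratio in the model the Krt19 call was lost (0.85, adjusted p = 0.051). The Abcb11 call was lost with that ratio (adjusted p = 0.55), with the mean 3'/5' ratio (0.098), with the control level (adjusted p = 0.088), after another quantile normalization (0.057), with array weights (0.060), without the 6 narrow arrays (0.28) and without vehicle 24 h replicate 3, ANIT 24 h replicate 1 or 3, vehicle 120 h replicate 3 or ANIT 120 h replicate 4 (adjusted p up to 0.054). No call was made for Cyp7a1 (0.96 ± 0.63, adjusted p = 0.31), Mki67 (0.96 ± 0.62, adjusted p = 0.30), Col1a1 (0.88 ± 0.34, adjusted p = 0.081) or Hmox1 (-0.19 ± 0.25, adjusted p = 0.62). Leaving out vehicle 24 h replicate 1 gave Mki67 an adjusted p of 0.035, and leaving out ANIT 24 h replicate 5 gave Col1a1 one of 0.0034, which was also called without ANIT 120 h replicate 1 and after another quantile normalization (adjusted p = 0.037).

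In all, 1924 genes had a different effect at the 2 times, 448 with a higher and 1476 with a lower effect at 120 h, and 72 and 371 differed at least 2-fold. The model with the control level called 1748, 821 and 927, of which 1235 were shared. The share of higher calls was 23.3% as deposited, 47.0% with the control level, 36.5% after another quantile normalization, 12.1% after shifting the arrays to a common median and 60.6% without the 6 narrow arrays. It was 44.1% of 438 calls with the beta-actin ratio, 31.8% of 1231 with the mean 3'/5' ratio and 48.9% of 1137 with the beta-actin ratio and the control level. The count was 3148 without vehicle 24 h replicate 1.

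Among lists, 13 of 31 had a different effect, 7 higher and 6 lower at 120 h, and 8 with an estimated correlation. Other splits of the same arrays called a median of 4 lists and at most 13. Lower were cholesterol synthesis (17 of 19 members fell, 18 when adjusted over the list alone, median -1.45, camera adjusted p = 1.5e-18) and ER stress (14 of 22 fell, 16 over the list alone, median -0.72, adjusted p = 2.2e-11). Lower too were acute phase proteins (12 of 23 fell, 13 over the list alone, median -0.29, adjusted p = 1.6e-06), fatty acid synthesis (7 of 16 fell, 8 over the list alone, median -0.72, adjusted p = 2.5e-05) and immediate early genes (11 of 22 fell, 12 over the list alone where 1 rose, median -0.82, adjusted p = 2.5e-05). Nrf2 targets (5 of 21 fell, 11 over the list alone, median -0.51, adjusted p = 0.0099) were also lower (adjusted p = 0.44 with an estimated correlation). The Nrf2 call was lost after another quantile normalization (median -0.45, adjusted p = 0.060), when dim genes were left out (adjusted p = 0.49), with the band as a block (adjusted p = 0.10), with the beta-actin ratio (median -0.17, adjusted p = 0.10) and without the 6 narrow arrays (median -0.036, adjusted p = 0.13). Higher were bile acid synthesis (4 of 12 rose, also over the list alone, median 0.38, adjusted p = 0.00016) and lymphocyte markers (2 of 16 rose, 3 over the list alone, median 0.36, adjusted p = 0.00017). So were cholangiocyte markers (6 of 25 rose and 3 fell, 7 and 3 over the list alone, median 0.29, adjusted p = 0.0015) and mitosis (3 of 31 rose, 0 over the list alone, median 0.30, adjusted p = 8.3e-05, adjusted p = 0.18 with an estimated correlation). Among genes at or above the median level the cholangiocyte median was -0.31 and the call was lost (adjusted p = 0.86). The mitosis call was lost without the 6 narrow arrays (median 0.13, adjusted p = 0.14) and with the beta-actin ratio and the control level (adjusted p = 0.19). Uptake transporters (3 of 7 rose, also over the list alone, median 0.33, adjusted p = 0.027, adjusted p = 0.19 with an estimated correlation), stellate cell and matrix genes (6 of 33 rose and 4 fell, 7 and 4 over the list alone, median 0.23, adjusted p = 0.028, adjusted p = 0.50 with an estimated correlation) and urea cycle genes (5 of 22 rose and 2 fell, 6 and 3 over the list alone, median 0.19, adjusted p = 0.042, adjusted p = 0.61 with an estimated correlation) were higher too. The uptake call was lost without ANIT 120 h replicate 3 (adjusted p = 0.052). The matrix call was lost with the beta-actin ratio (adjusted p = 0.079) and without vehicle 24 h replicate 1, ANIT 24 h replicate 1, vehicle 120 h replicate 1 or 2 or ANIT 120 h replicate 3 (adjusted p up to 0.077). The urea cycle call was lost after the median shift and with probe set means (adjusted p = 0.057 and 0.063). It was lost without vehicle 24 h replicate 1 (0.20, the highest) or 6, ANIT 24 h replicate 2, 4 or 5, vehicle 120 h replicate 1, 2 or 6 or ANIT 120 h replicate 1 or 3. The fatty acid oxidation list (median 0.20, adjusted p = 0.13) was called with the control level (median 0.29, adjusted p = 0.0062), after another quantile normalization (0.018), and without the 6 narrow arrays (median 0.38, adjusted p = 2.5e-06). It was also called without vehicle 24 h replicate 4 (0.024), ANIT 24 h replicate 2 or ANIT 120 h replicate 4. The endothelial list was called with the control level (median 0.31, adjusted p = 0.028). The growth hormone axis list (median 0.13, adjusted p = 0.13) was called after another quantile normalization (adjusted p = 0.039), when dim genes were left out (0.0019), with the band as a block (0.017) and without the 6 narrow arrays (median 0.35, adjusted p = 0.033). When dim genes were left out, the P450, Kupffer cell, circadian and fatty acid oxidation lists were called (adjusted p = 0.0041, 0.049, 0.027 and 0.0041), the circadian list with a median of -0.06 against 0.09 over all genes. The Kupffer cell list was also called after another quantile normalization (adjusted p = 0.024) and, like the fatty acid oxidation list, with the beta-actin ratio (adjusted p = 0.023 for both, and 0.0041 for the latter with the mean 3'/5' ratio), and the efflux list with only the wide arrays (adjusted p = 0.040). By fry, the matrix and urea cycle lists were not called (adjusted p = 0.20 and 0.23). The interferon list (adjusted p = 0.13) was called with the band as a block (0.017), without the 6 narrow arrays (0.024), and without ANIT 120 h replicate 6 (0.032), vehicle 24 h replicate 3 or vehicle 120 h replicate 1. The median and mean of the P450 list (0.27 and -0.20) and the efflux list (0.01 and -0.25) did not give 1 direction, nor did those of the hepatocyte secreted proteins (0.03 and -0.05), the endothelial markers (0.05 and -0.02) and the chemokine list (0.00 and -0.23). Both were negative for the p53 list (-0.05 and -0.12), where camera's direction was up.

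As deposited, sharing with 120 h exceeded that of independent lists for genes lower at 24 h, but no excess passed the test for higher ones. Lcn2 was 1 of the 12 of 1738 genes that were higher at both times, where independent lists would share 8.92 (Fisher's exact p = 0.28). Of the 713 genes lower at 24 h 61 were still lower, where 10.8 would be shared (odds ratio 8.29, Fisher's exact p = 5.7e-30). Fisher's test takes genes as independent, so its p says nothing of rats. Both comparisons use 1 variance per gene, so the excess alone shows no persistence. With the control level 27 of 1293 were still higher (24.3 expected, Fisher's exact p = 0.59). There 134 of 1407 were still lower (44.1 expected, Fisher's exact p = 3.6e-34). Without the 6 narrow arrays 16 of 821 were still higher and 17 of 733 still lower. With the array SD as a covariate they were 48 of 1485 and 102 of 1420, and with the beta-actin ratio 3 of 462 and 30 of 445. The median change of genes lower at 24 h was -0.52 then and -0.08 at 120 h. That of genes higher at 24 h was 0.57 and -0.09. The sign at 24 h was kept at 120 h by 61.9% of the lower and 32.6% of the higher genes. In the control level fit 60.2% and 49.3% did, and its higher genes had a 120 h median of -0.0036. The 2 comparisons use different vehicle rats. While 73 calls kept their sign, more than expected reversed too: 31 higher genes (26.3 expected) and 11 lower ones (3.66 expected). The 73 fell to 46 without ANIT 120 h replicate 6 and to 47 without vehicle 120 h replicate 3 or 5.

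**Figure D4:**
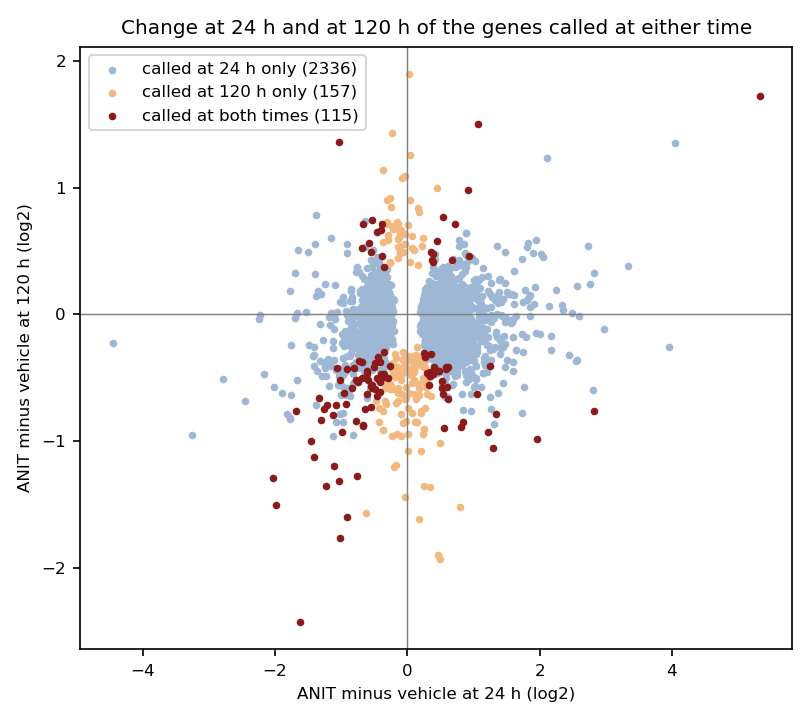
Each point is 1 gene called at 24 h or at 120 h, with the log2 change from vehicle at 24 h on the horizontal and at 120 h on the vertical axis. Of these genes, 2336 were called at 24 h only, 157 at 120 h only and 115 at both times.

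The vehicle groups differed in 1 gene, Gpt, the alanine aminotransferase gene, which was higher at 120 h (1.04 ± 0.16, limma adjusted p = 0.0074), and 1639 genes had an unadjusted p under 0.05. Counts over alternatives went from 0 with only the 12 vehicle arrays to 149 with array weights and 175 without vehicle 24 h replicate 1. Of the 31 lists 3 were called between these groups. Cholesterol synthesis was lower at 120 h (0 of 19 rose, 0 fell, 10 falling when adjusted over the list alone, median -0.30, camera adjusted p = 1.2e-10, adjusted p = 0.23 with an estimated correlation). Urea cycle genes were higher (8 rising and 1 falling when adjusted over the list alone, median 0.20, adjusted p = 0.00041, adjusted p = 0.45 with an estimated correlation), as were fatty acid oxidation genes (2 rising when adjusted over the list alone, median 0.20, adjusted p = 0.0027, adjusted p = 0.57 with an estimated correlation). The fatty acid synthesis list (median 0.04, mean 0.12) and the immediate early list (median 0.09, mean 0.02) had a camera direction down. By fry, 0 lists moved one way between the vehicle groups.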

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

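The tests of the array spread, of the 3'/5' ratios, of the share of higher calls and of the cholangiocyte markers were chosen after those results were seen, while the counts of other splits were planned.

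The first pattern is that the main axis of variation followed the spread of values within an array. Its variance lay to 66.4% within the 4 groups, which argues against ANIT treatment as its whole source. A part tied to ANIT stays open. At 24 h the component averaged -20.0 in ANIT and 13.1 in vehicle rats (exact permutation adjusted p = 0.044, and 0.36 at 120 h). It followed the level of the spiked controls (r = 0.92), so the amount of labelled target on an array is a candidate source, although within the narrow, middle and wide arrays, which were formed from array SD and so span a narrower range, r was 0.42, 0.29 and 0.22. RNA degradation stays open: r with the mean 3'/5' control ratio was -0.44 (permutation p = 0.034, adjusted p = 0.056), and with the beta-actin ratio alone -0.55 (adjusted p = 0.012), or -0.45, -0.86 and -0.83 within the bands. The beta-actin ratio was also higher in ANIT than in vehicle rats at 24 h (3.12 and 2.84, exact permutation adjusted p = 0.017). A hybridisation or scan batch, which no label used here gives, stays open untested.

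The second pattern is that 70.9% of the genes called at 24 h were higher. With the control level in the model the share was 47.9%, so a difference in labelled target between the groups may account for the imbalance. It was 81.2% after shifting the arrays to a common median and 50.9% with the beta-actin 3'/5' ratio in the model. The ratio did not overlap between the groups and 0 genes were related to it, so RNA quality stays undecided. A larger number of genes raised than lowered by ANIT stays open. The share was 53.3% among the 9 middle and 44.1% among the 9 wide arrays, but these hold 2 and 1 vehicle arrays of 24 h, too few to decide.

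The third pattern is that cholangiocyte and ductular markers were higher at 120 h. A lower share of hepatocytes stays open. The cholangiocyte score exceeded the endothelial score by 0.35 in ANIT rats relative to vehicle (exact permutation p = 0.0065, adjusted p = 0.021). The excess lay above every vehicle rat in 4 of 6. That cannot decide, since of the cell scores only the endothelial one did not rise (-0.059). The lymphocyte, monocyte and stellate cell scores were higher by 0.16, 0.25 and 0.23 (exact permutation adjusted p = 0.0094, 0.044 and 0.044). The Kupffer cell score was 0.14 higher (adjusted p = 0.13). The list of hepatocyte secreted proteins was lower (median -0.05, camera adjusted p = 0.012, or 0.20 with an estimated correlation). With the control level in the model the cholangiocyte list was still called (camera adjusted p = 3.6e-09), which argues against labelled target as the whole cause, and a change in the bile duct cells themselves stays a hypothesis. Of the 25 measured markers 6 lay at or above the median of all genes in vehicle rats, and the most abundant, Krt18, Krt8 and Cldn3, changed by -0.01, 0.14 and -0.00 at 120 h.

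Other splits of the same arrays gave the following. For genes called at 24 h, 2 of 100 splits gave as many, the real one included (2451, highest other 3074), so chance is unlikely by the share. The larger split exchanged 2 arrays and had a control level difference of -0.41 against -0.35 in the real one. With the control level in the model it was 1 of 100 (2700, highest other 741). For 120 h, 1 of 100 gave as many (272, highest other 2), and 1 of 100 with the control level (674, highest other 12). For the difference between times it was 1 of 100 (1924, highest other 1). Chance is excluded for these and for the lists called at 120 h, 1 of 100 (13, highest other 12, median other 2). It is not excluded for the vehicle groups, 5 of 100 (1, highest other 1), for the lists called at 24 h, 7 of 100 (14, highest other 15, median other 6), or for the lists that differed between times, 6 of 100 (13, highest other 13, median other 4). For changes still present at 120 h it was 1 of 100 (73, highest other 0). Other splits called at most 2 genes at 120 h, so that count decides nothing about sharing.

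Of 282 groups of 6 arrays, 22 held an array far from the others, where chance gives about 1 in 20, or 14.1. ANIT 24 h replicate 2 held 5 of them: against the mean of the other 5 rats it lay at -1.69 for Lcn2, 1.81 for Hsd17b2, 0.95 for Nr1h4, 0.45 for Cpt1a and 0.88 for Hlf, each toward the vehicle level. Vehicle 24 h replicate 1 lay at -2.78 for Mki67, -0.71 for Cxcl2 and 0.97 for Gpt. Vehicle 120 h replicate 3 lay at 0.31 for Abcb11, 0.52 for Prom1 and 0.65 for Cftr. Vehicle 24 h replicate 4 lay at 1.70 for Idi1 and -0.65 for Cpt1a, and ANIT 120 h replicate 3 at 1.25 for Hsd17b2 and 0.98 for Tor3a. The others were Amigo3 in ANIT 24 h replicate 6 (0.88), Nrep in vehicle 24 h replicate 5 (-1.20), Col1a1 in ANIT 24 h replicate 5 (1.60), Hmmr in vehicle 24 h replicate 3 (0.52), Pde4b in vehicle 120 h replicate 1 (-1.14), Cd163 in ANIT 120 h replicate 2 (0.51) and Gpt in vehicle 120 h replicate 4 (0.44).

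By the test of the difference itself, 1924 genes had another ANIT effect at 120 h than at 24 h. Among lists the median difference was 0.38 for bile acid synthesis, 0.33 for uptake transporters, -0.51 for Nrf2 targets, -0.29 for acute phase proteins, 0.29 for cholangiocyte markers, 0.23 for stellate cell and matrix genes and 0.30 for mitosis. It was -1.45 for cholesterol synthesis, 0.36 for lymphocyte markers, -0.72 for fatty acid synthesis, 0.19 for urea cycle genes, -0.82 for immediate early genes and -0.72 for ER stress genes. For genes it was 4.22 for Nrep, 2.39 for Siglec5, 2.30 for Hsd17b2, 2.27 for Nim1k, 2.22 for Fmo1, -4.21 for A2m, -3.60 for Lcn2, -3.59 for Sqle, -3.41 for Idi1 and -3.08 for Amigo3. It was also 0.88 for Krt19, 0.58 for Slc10a1, -0.53 for Abcb11 and -2.32 for Nr0b2. Of 117 named genes, 79 differed between the times.

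After leaving out 91 control probe sets, 11980 probe sets without a single gene name entered no comparison, and 1018 of them were called at 24 h and 80 at 120 h by limma. The control level, in probe sets outside the comparisons of genes, was 0.15 higher in ANIT than in vehicle rats at 120 h (exact permutation p = 0.46).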

How the results depend on the processing

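The fits with the control level, the 3'/5' ratios, the array SD, the bands of arrays and without narrow arrays were chosen after seeing the data, and the others were planned. Of 131 gene calls named or fixed, 57 held in every alternative run for them, 74 were lost in at least 1 and 1 of these reversed, Cd79b at 24 h with the beta-actin ratio (0.0035, adjusted p = 0.996) and with that ratio and the control level (0.010, adjusted p = 0.972), while 8 uncalled genes were called in some alternative. Of 40 list calls 14 held in every alternative run for them and 26 were lost in some, 26 uncalled list results were called in some alternative and 2 list results reversed. Leaving out dim genes gave a value for 124 of 149 gene and 78 of 93 list results, and the fit with only the middle arrays for 76 and 31. Where a value moved, the cause was not tested, except that higher minimum folds leave fewer calls by construction. Signal over background was not analysed here.

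Genes called at 24 h numbered 3687 with every probe set on its own, 1111 at 1.5-fold, 293 at 2-fold, 1554 without the 6 narrow arrays, 776 with only the wide, 1054 with only the middle arrays and 907 with the beta-actin ratio. At 120 h they numbered 460 after another quantile normalization, 143 after the median shift, 134 at 1.5-fold, 35 at 2-fold, 176 with only the 12 arrays of that time, 674 with the control level, 652 with the array SD, 156 with the mean 3'/5' ratio, 627 with the beta-actin ratio and the control level and 43 with only the wide arrays. Genes that differed between times numbered 443 at 2-fold, 438 with the beta-actin ratio, 1231 with the mean ratio, 1137 with the beta-actin ratio and the control level, 852 without the narrow and 207 with only the wide arrays. Between the vehicle groups 1 gene became 17 after quantile normalization, 12 among genes at or above the median level, 3 with probe set means, 6 with every probe set, 13 with trend and robust prior, 149 with array weights, 0 with only the vehicle arrays, 3 with the control level, 3 with the array SD, 2 with bands as a block, 2 with the beta-actin ratio, 3 with that ratio and the control level, 0 without narrow arrays, 0 with only the wide and 2 with only the middle arrays. Changes of 24 h still present at 120 h numbered 113 after quantile normalization, 42 after the median shift, 30 at 1.5-fold, 161 with the control level, 150 with the array SD, 33 with the beta-actin ratio, 44 with the mean ratio, 33 without narrow arrays and 9 with only the wide arrays. With an estimated correlation 7 lists were called at 24 h, 2 at 120 h and 8 for the difference, and with only the wide arrays 5 at 120 h. Camera's direction for the mitosis list turned at 120 h without the narrow arrays, where the median kept its sign (0.0043, adjusted p = 0.80), and with only the wide arrays, where the median turned too (-0.030, adjusted p = 0.63). For the difference it turned with only the wide arrays while the median kept its sign (0.020, adjusted p = 0.83). At 24 h the median of that list was -0.22 over all arrays and 0.0086 with only the wide arrays (adjusted p = 0.91).

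Leaving out 1 array gave 1829 (without ANIT 24 h replicate 6) to 3534 genes (without vehicle 24 h replicate 1) at 24 h. At 120 h it gave 152 to 343 (without ANIT 120 h replicate 3). For the difference it gave 1430 to 3148, for the same arrays as at 24 h. For the vehicle groups it gave 1 to 175 (without vehicle 24 h replicate 1). It gave 2 without vehicle 120 h replicate 3 or 6 or ANIT 120 h replicate 1, 3 or 6. For changes still present it gave 46 to 85 (without ANIT 120 h replicate 3). Lists ran from 12 to 14 at 24 h, 11 to 16 at 120 h and 10 to 14 for the difference.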

Other observations

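The values in this part were chosen after the results were seen, and no hypothesis was tested.

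Among genes called at both times, 42 changed direction, and with the control level in the model 32 of these were called at both times. Genes higher at 24 h and lower at 120 h included Fabp2, an intestinal-type fatty acid binding protein (log2 change 1.30, then -1.06, limma adjusted p = 9.0e-05 and 0.0087), Cyp1a2 (0.85, then -0.85), Cavin3 (1.35, then -0.78), the amino acid carrier gene Slc3a2 (1.05, then -0.63) and Eprs1, an aminoacyl-tRNA synthetase (1.25, then -0.41). Genes lower at 24 h and higher at 120 h included Siglec5 (-1.03, then 1.36), Cd24 (-0.38, then 0.72), Prom1 (-0.39, then 0.66), the cell cycle inhibitor gene Cdkn1c (-0.53, then 0.74) and the iron exporter gene Slc40a1 (-0.35, then 0.38). These genes were picked after their values were seen.

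Of the 31 genes that were higher and then lower, 5 were cholesterol synthesis genes, Cyp51, Msmo1, Nsdhl, Sc5d and Sqle, a list that had already been seen to be called higher at 24 h and lower at 120 h. With the control level in the model Sc5d was not called at 24 h (adjusted p = 0.063). At 120 h the calls of Msmo1 and Sqle were lost without vehicle replicate 3 or 5, among others (adjusted p of up to 0.11). The cholesterol synthesis list was also lower in vehicle rats of 120 h than of 24 h (median -0.30). The 2 comparisons use different vehicle rats, so a change within an animal was not measured.

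Probe sets of 1 gene did not always give 1 size. At 24 h those of Acaca ran from 0.08 to 1.10 and those of Lss from 1.09 to 2.18, and at 120 h those of Pde4b ran from 0.04 to 1.0 and those of Dusp1 from -0.85 to -0.11.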
